A study of Linum usitatissimum with 8 samples.

How the data were processed

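Gene expression was measured by RNA sequencing in seeds of flax (Linum usitatissimum), cultivar Heiya No.14. Per the labels, the seeds were of 4 developmental stages named DAP5, DAP10, DAP20 and DAP30, each with 2 replicates, which gives 8 libraries. The labels do not spell the stage names out, and they are used here as given. Total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The aligner, the counting tool, their versions and the genome build are not given in the sources used here, and neither is whether strand was used in counting.

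The authors deposited 1 table of whole-number read counts per gene and library, with no normalization, and a gene length per row. How that length was defined is not given in the sources used here. The table held 40518 rows. Of these, 38306 carried annotated gene IDs and 2212 were taken as gene models added by the authors, from the word newGene in the ID. No row lacked a gene ID, and 4546 rows were at 0 in every library. The file does not pair gene IDs with names or descriptions, and no annotation or coordinates were used here. Genes are therefore given by ID, and reads shared between near-identical copies or overlapping genes could not be recognised.

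Library totals ran from 12951493 to 27691831 counts, a ratio of 2.14. Each column was matched to its sample through the library code in the sample's description. The table was analysed in R 4.3.3 with edgeR 4.0.16, on the counts as deposited. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 28749 genes, 1295 of them added models. Libraries were scaled by TMM, which assumes that most genes do not change. All 8 libraries entered 1 quasi-likelihood fit with stage as the only term, so that the stages shared an estimate of the spread. The 6 pairs of stages were tested with glmQLFTest, and a joint test covered all 4 stages. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a false discovery rate (FDR) below 0.05 was called a change. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of F.

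Expression levels are given as CPM, the count of a gene scaled to a common library size. Levels of single genes use TMM scaling, while detection at 1 CPM uses library totals. Library totals also serve for the counts of genes with at least 10 CPM at 1 stage and no count, or a mean below 0.5 CPM, at another. A fold against a stage with no count in either library is a lower bound, set by 3 counts summed over both libraries of that stage. Leaving out 1 of these libraries lowers each such bound by 1.74 to 2.34 times by construction, since the same 3 counts then rest on less depth. The fitted log2 fold change of such genes depends on the prior count of the fit and is not given. With few counts at 1 stage, the ratio of summed counts is given with an exact 95% binomial interval. Intervals and floors cover counting error only. The effective number of genes of a library is the exponential of the Shannon entropy of its count shares. Library measures were compared between stages by exact permutation tests over the 105 divisions of the libraries into 4 pairs, and 8 such measures formed 1 family. The p-value is the share of divisions with squared deviations within pairs that sum to no more than those within stages. It takes no account of the order of the stages or the direction of a change.

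The design, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for the steps DAP5 to DAP10, DAP10 to DAP20 and DAP20 to DAP30 and for the span DAP5 to DAP30, the 2 IDs with the largest rise and the 2 with the largest fall by log2 fold change. These had to have an FDR below 0.05, a mean of at least 10 CPM over all libraries, and both libraries of 1 stage above both of the other. The ranking uses the fitted log2 fold change, so genes with no count at 1 stage are not ranked by a measured fold. A further 23 gene lists, chosen by words in gene names, were not tested because the table holds no names. Sets of the 100 most abundant genes per stage were chosen after the data were examined.

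The test was run on simulated counts drawn from the means and library sizes of these data, with 50 genes changed at each of 4 fold sizes. For DAP5 to DAP10 it recovered 16% of genes changed 2-fold, 74% of those changed 4-fold and 92% of those changed 8-fold. For DAP10 to DAP20 the shares were 26%, 76% and 78%, for DAP20 to DAP30 they were 14%, 72% and 84%, and for DAP5 to DAP30 they were 18%, 72% and 88%. Calls on unchanged genes made up 3.55%, 5.59%, 5.19% and 2.88% of all calls in these 4 comparisons. With so few changed genes the FDR threshold is stricter than in the real comparisons. Each simulated gene took the spread of the fitted trend, alike at every stage, whereas the real replicates differed most at DAP20. These shares therefore hold for the simulated data only.

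The alternatives were DESeq2 size factors or library totals in place of TMM, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom from limma 3.58.1, a test against a 2-fold change, a fit of only the 2 stages compared, the replicate number as a block, and leaving out each library in turn.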

Results

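RNA was sequenced from flax seeds of the cultivar Heiya No.14 at 4 developmental stages, labelled DAP5, DAP10, DAP20 and DAP30, with 2 libraries per stage. The study set out to compare gene expression among these stages. Library totals were 26500842 and 27691831 counts at DAP5, 15150199 and 12951493 at DAP10, 22238190 and 19500351 at DAP20, and 21208377 and 16575103 at DAP30. Nothing in the labels says that the 2 replicates of a stage came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

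Libraries of the same stage resembled each other more than libraries of different stages. Across 28749 genes, which are not independent replicates, the Pearson correlation of log2 CPM ran from 0.949 to 0.977 between replicates and from 0.543 to 0.898 between stages. The lowest replicate correlation was that of DAP20. All replicate pairs differed by more than counting noise, with a chi-square of at least 19.53 per degree of freedom, so each library was counted as its own sample. The first principal component held 70.8% of the variance and placed the stages in the order DAP5, DAP10, DAP20 and DAP30, while the second held 13% and set DAP10 and DAP20 apart from DAP5 and DAP30.

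**Figure D1:**
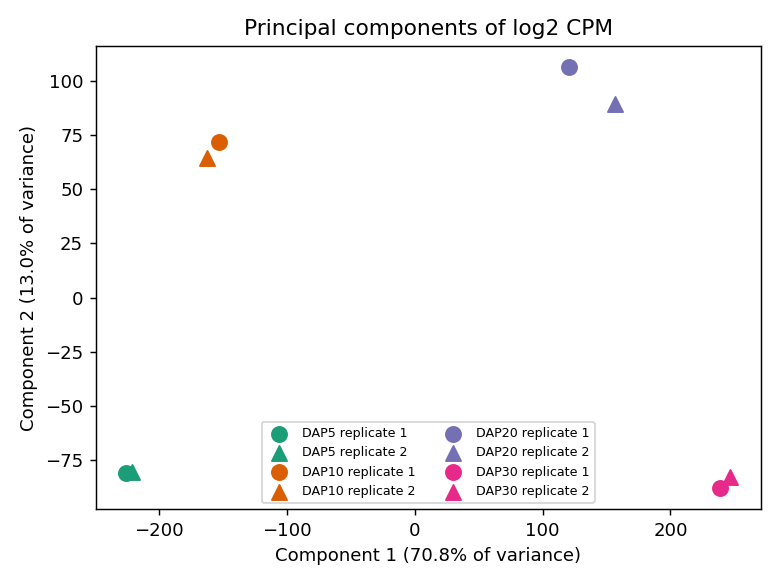
Principal components of log2 CPM for the 8 libraries, with component 1 (70.8% of the variance) on the horizontal axis and component 2 (13%) on the vertical axis. Colours mark stages, circles replicate 1 and triangles replicate 2, and the libraries of each stage lie next to each other.

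Counts were spread over many genes at DAP5 and concentrated in fewer genes at the later stages. The effective number of genes was 10084 ± 418 at DAP5, 5504 ± 196 at DAP10, 3119 ± 77.1 at DAP20 and 3596 ± 394 at DAP30 (SD, n = 2, exact permutation p = 0.00952, the smallest that 105 divisions can give, adjusted p = 0.0152). The 100 most abundant genes of each library took 11.6% ± 0.714 of the counts at DAP5, 23.9% ± 0.714 at DAP10, 33.0% ± 1.20 at DAP20 and 29.1% ± 2.19 at DAP30 (SD, n = 2, exact permutation p = 0.00952, adjusted p = 0.0152). At DAP5 the most abundant gene held 0.436% and 0.341% of the counts of replicates 1 and 2. At DAP20 Lus10004895.g.BGIv1.0 held 3.74% and 4.58%. The number of genes at 1 CPM or more was 25527 ± 170 at DAP5, 24756 ± 129 at DAP10, 22116 ± 295 at DAP20 and 20330 ± 182 at DAP30 (SD, n = 2, exact permutation p = 0.00952, adjusted p = 0.0152). Because 1 CPM is taken on library totals, a concentration of counts in fewer genes can itself lower this number, so it is not separate evidence. These permutation tests ask whether libraries of a stage resemble each other, and the direction between stages was not tested.

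**Figure D2:**
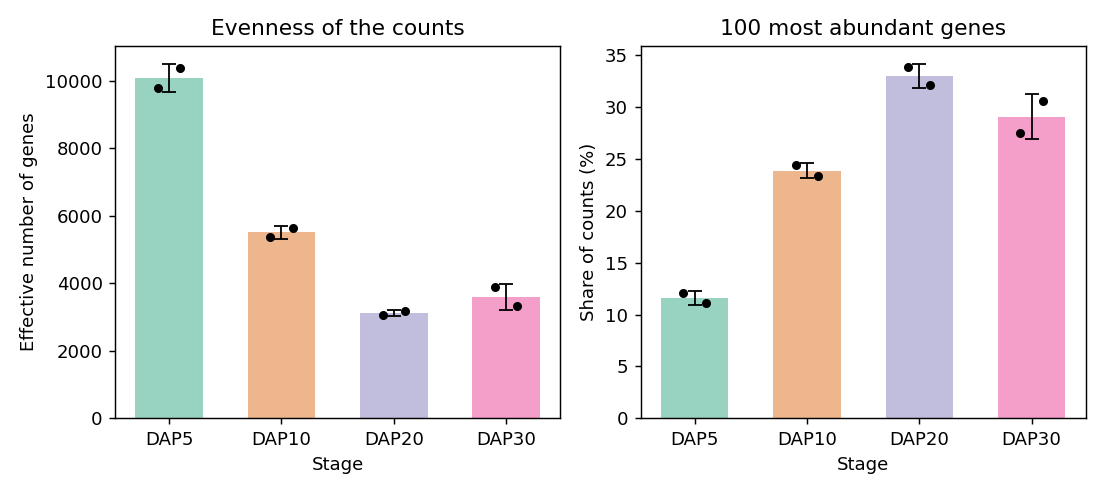
Left, the effective number of genes per stage. Right, the share of counts in the 100 most abundant genes, in percent. Bars are means, error bars the SD and points the 2 libraries of each stage. The effective number was highest at DAP5 (10084) and lowest at DAP20 (3119).

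The sets of abundant genes differed between stages. Of the 100 genes with the highest mean share at DAP5, 48 were also among the 100 of DAP10, 20 among those of DAP20 and 18 among those of DAP30. The sets of DAP20 and DAP30 shared 64 genes. The 100 most abundant genes of DAP20 held 3.19% ± 0.148 of the counts at DAP5, 15.9% ± 0.584 at DAP10, 32.8% ± 1.34 at DAP20 and 25.6% ± 2.04 at DAP30 (SD, n = 2). These sets were picked on the same libraries, so a set's high level at its own stage is not independent evidence.

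Of the 28749 genes tested, 22726 (79.0%) changed across the 4 stages in the joint test (edgeR, FDR below 0.05). The stage with the highest mean was DAP5 for 7241 of them, DAP10 for 4779, DAP20 for 3544 and DAP30 for 7162. With library totals in place of TMM, 23492 genes changed and the peaks were more often early, with 12600 genes highest at DAP5, 4093 at DAP10, 2267 at DAP20 and 4532 at DAP30. Over the 3 steps between consecutive stages, 2603 genes rose in at least 2 steps and never fell, 2448 fell in at least 2 steps and never rose, and 4030 both rose and fell. No step was called for 8146 genes.

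From DAP5 to DAP10 a group of genes that were later the most abundant in the seed had already begun to rise. Of the 100 most abundant genes of DAP20, a set picked without the DAP5 and DAP10 libraries, 74 rose and 26 were not called, with a median log2 fold change of 2.23. With library totals in place of TMM, 62 of them rose. Among single genes Lus10010341.g.BGIv1.0 rose from 0.101 ± 0.104 to 1030 ± 386 CPM (SD, n = 2), a log2 fold change of 13.20 ± 0.69 (SE, edgeR FDR = 0.000132). It had 8 counts at DAP5 and 32113 at DAP10, a ratio of 10100 with an exact binomial interval of 5120 to 23400, and the log2 fold change was 12.47 without DAP5 replicate 1 and 14.89 without DAP5 replicate 2. Lus10024931.g.BGIv1.0 had no count at DAP5 and rose to 75.4 ± 56.4 CPM (SD, n = 2), at least 2010-fold higher (edgeR FDR = 0.00073), or at least 912-fold without DAP10 replicate 1. Its level was 0.741 ± 0.167 CPM at DAP20.

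In the same step Lus10030912.g.BGIv1.0 fell from 57.2 ± 2.81 CPM (SD, n = 2) to no count in either DAP10 library, at least 586-fold lower (edgeR FDR = 0.00029). Lus10024035.g.BGIv1.0 fell from 54.1 ± 8.91 CPM (SD, n = 2) to no count, at least 550-fold lower (edgeR FDR = 0.000645), and had no count at DAP20 or DAP30 either. In all, 6772 genes (23.6%) changed, of which 3564 rose and 3208 fell, and 4722 of them had a fitted change of at least 2-fold (4720 with genes at 0 in 1 stage set to their bound). Of the called genes, 52.6% rose under TMM and 23.1% under library totals, where the median log2 fold change of all genes was -0.395 in place of -0.015. With only these 2 stages in the fit, 9671 genes were called. The count was 1818 without DAP10 replicate 1, 2103 without DAP10 replicate 2, 3376 without DAP5 replicate 1, 3156 without DAP5 replicate 2, and 1683 in a test against a 2-fold change.

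From DAP10 to DAP20 most genes that were abundant at DAP5 fell, and most of those abundant at DAP30 rose. Of the 100 most abundant genes of DAP5, a set picked without the DAP10 and DAP20 libraries, 60 fell and 4 rose, with a median log2 fold change of -1.70. Of the 100 most abundant genes of DAP30, likewise picked on other libraries, 72 rose and 2 fell, with a median of 2.58. Both directions held under library totals, with 69 of the first set falling and 66 of the second rising. Lus10004895.g.BGIv1.0 had no count in any DAP5 or DAP10 library and rose to 50100 ± 7820 CPM at DAP20 (SD, n = 2), at least 508000-fold higher than at DAP10 (edgeR FDR = 6.75e-05), which made it the most abundant gene of that stage. Lus10040687.g.BGIv1.0 rose from no count to 276 ± 137 CPM (SD, n = 2), at least 2890-fold higher (edgeR FDR = 7.71e-05), or at least 1830-fold without DAP20 replicate 1.

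Both genes with the largest fall in this step peaked at DAP10. Lus10025231.g.BGIv1.0 fell from 537 ± 75.4 CPM (SD, n = 2) to no count, at least 6160-fold lower (edgeR FDR = 0.00137), and Lus10032460.g.BGIv1.0 fell from 225 ± 5.34 CPM (SD, n = 2) to no count, at least 2600-fold lower (edgeR FDR = 4.26e-05). At DAP5 their levels were 27.0 ± 32.7 and 0.0668 ± 0.0594 CPM (SD, n = 2). Genes with at least 10 CPM in both DAP10 libraries and no count at DAP20 numbered 53, and 10 genes did the opposite. The numbers were 354 and 75 with a mean below 0.5 CPM in place of no count. These counts of genes use library totals, which favour falls in this step, and were not repeated under TMM. In all, 15323 genes (53.3%) changed, of which 7332 rose and 7991 fell, and 11711 had a fitted change of at least 2-fold (11698 with genes at their bound). Of the called genes, 47.8% rose under TMM and 30.1% under library totals, where the median log2 fold change of all genes was -0.425 in place of -0.0322. The count was 10010 without DAP10 replicate 2 and 7508 in a test against a 2-fold change, and the number of genes that rose was 4817 without DAP10 replicate 1 and 4441 without replicate 2.

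From DAP20 to DAP30 more genes lost than gained expression among those that changed strongly. Of the genes that passed a test against a 2-fold change, 1703 fell and 528 rose. Genes with at least 10 CPM in both DAP20 libraries and no count at DAP30 numbered 36, whereas no gene went the opposite way. The numbers were 138 and 0 with a mean below 0.5 CPM in place of no count. These counts of genes use library totals, under which the median log2 fold change of all genes was -0.139 in place of -0.0407 under TMM. The genes abundant at DAP5, picked without these libraries, had 29 members that fell, 13 that rose and 58 that were not called. Among genes with a mean of at least 10 CPM over all libraries, the 2 largest rises were small beside those of the earlier steps. Lus10028448.g.BGIv1.0 rose from 7.20 ± 8.94 to 121 ± 0.238 CPM (SD, n = 2), a log2 fold change of 4.05 ± 0.98 (SE, edgeR FDR = 0.0187), and its 2 DAP20 libraries differed so widely that the log2 fold change was 7.11 without DAP20 replicate 1 and 3.17 without replicate 2. The added model Linumusitatissimum_newGene_1480 rose from 2 to 33 counts summed over the libraries, a ratio of 19.5 with an exact binomial interval of 4.98 to 168 (edgeR FDR = 0.0322). It reached the mean of 10 CPM through DAP5 and DAP10, at 50.4 ± 37.9 and 379 ± 14.3 CPM (SD, n = 2).

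The 2 genes with the largest fall were among the abundant genes of DAP20. Lus10007186.g.BGIv1.0 fell from 6230 ± 4400 CPM (SD, n = 2) to no count in either DAP30 library, at least 58800-fold lower (edgeR FDR = 0.00364). Lus10000298.g.BGIv1.0 fell from 4940 ± 3250 CPM (SD, n = 2) to no count, at least 46700-fold lower (edgeR FDR = 0.00341). Without DAP20 replicate 1 these bounds were 91500 and 71000, and without DAP20 replicate 2 they were 30600 and 25900. Whether the 2 genes overlap or share reads was not checked here, and their replicates differed at the earlier stages, most at DAP10, where replicate 2 held 17.4 and 15.5 times the level of replicate 1. In all, 9338 genes (32.5%) changed, of which 4327 rose and 5011 fell, and 6381 had a fitted change of at least 2-fold (6351 with genes at their bound). Of the called genes, 46.3% rose under TMM, 38.1% under library totals and 53.2% by limma-voom, which called 4427 higher and 3894 lower. The calls numbered 4660 without DAP30 replicate 1, 5069 without DAP30 replicate 2, 5796 with only these 2 stages in the fit and 2231 in the test against a 2-fold change. Over the alternatives the FDR for Linumusitatissimum_newGene_1480 ran from 0.00103 to 0.271. It was not called by limma-voom (0.271), in the test against a 2-fold change, or with any 1 library of DAP10, DAP20 or DAP30 left out. Lus10028448.g.BGIv1.0 was not called in the test against a 2-fold change or with either DAP30 library left out. For Lus10007186.g.BGIv1.0 the FDR ran from 6.34e-17 to 0.0526, and it was not called by limma-voom (0.0526).

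**Figure D3:**
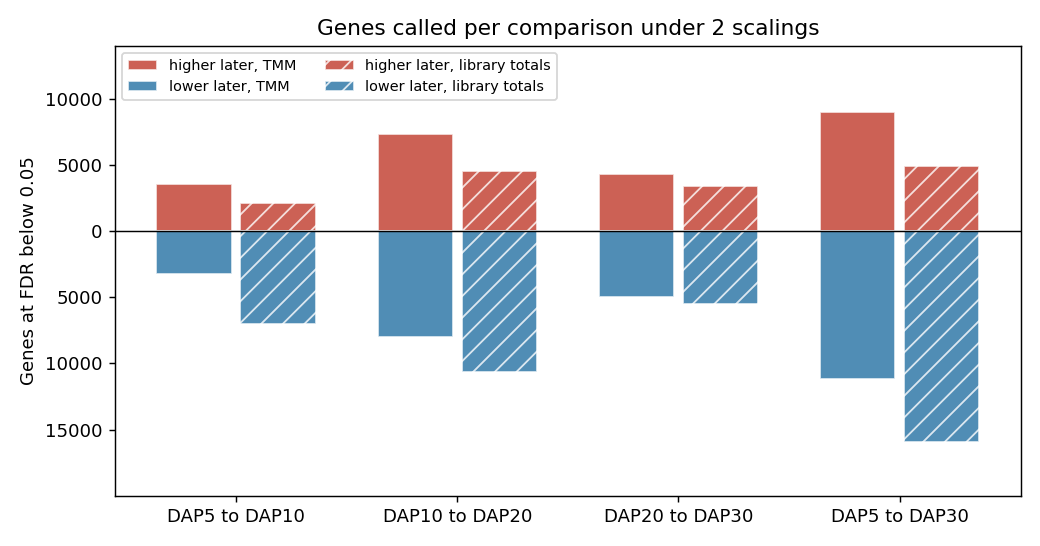
Genes at an FDR below 0.05 in 4 comparisons, with genes higher at the later stage above 0 and genes lower at the later stage below 0. Plain bars use TMM scaling and hatched bars library totals, and from DAP5 to DAP30 the count of higher genes was 8989 under TMM and 4960 under library totals.

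Across the whole span from DAP5 to DAP30 most of the genes tested changed, and more of them fell than rose. A test against a 2-fold change called 8250 genes lower and 5451 higher at DAP30. Genes with at least 10 CPM in both DAP5 libraries and no count at DAP30 numbered 357, and 15 genes did the opposite. No count is easier to reach at DAP30, where 3 counts over both libraries equal 0.0794 CPM, against 0.0554 CPM at DAP5. With a mean below 0.5 CPM in place of no count, which depends less on depth, the numbers were 1375 and 172. These counts of genes use library totals, and the same limits under TMM were not tried. Library totals favour falls over this span, with a median log2 fold change of all genes of -1.11 against -0.241 under TMM. How much of the imbalance comes from the scaling is therefore not known. Of the 100 most abundant genes of DAP20, a set picked without these libraries, 91 rose and 7 fell, with a median log2 fold change of 6.43, also with its 3 genes at 0 in 1 stage set to their bound. Lus10004895.g.BGIv1.0, with no count at DAP5, stood at 6220 ± 2010 CPM at DAP30 (SD, n = 2), at least 154000-fold higher (edgeR FDR = 2.71e-05) although below its DAP20 level. Lus10037043.g.BGIv1.0 rose from no count to 365 ± 132 CPM (SD, n = 2), at least 9010-fold higher (edgeR FDR = 1.2e-05), and had reached 322 ± 86.2 CPM by DAP20.

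Lus10039701.g.BGIv1.0 had means of 2100 ± 619 CPM at DAP5, 104 ± 32.9 at DAP10 and 0.545 ± 0.595 at DAP20 (SD, n = 2) and no count at DAP30, at least 20300-fold lower over the span (edgeR FDR = 3.21e-05). Lus10007186.g.BGIv1.0 fell from 1200 ± 540 CPM (SD, n = 2) to no count, at least 11900-fold lower (edgeR FDR = 0.00124), and its means in between were 4490 ± 5650 CPM at DAP10 and 6230 ± 4400 at DAP20 (SD, n = 2). In all, 20170 genes (70.2%) changed, of which 8989 rose and 11181 fell, and 16980 had a fitted change of at least 2-fold (16964 with genes at their bound). Of the called genes, 44.6% rose under TMM and 23.8% under library totals, where the median log2 fold change of all genes was -1.11 in place of -0.241 and 112 genes were called in the opposite direction.

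**Figure D4:**
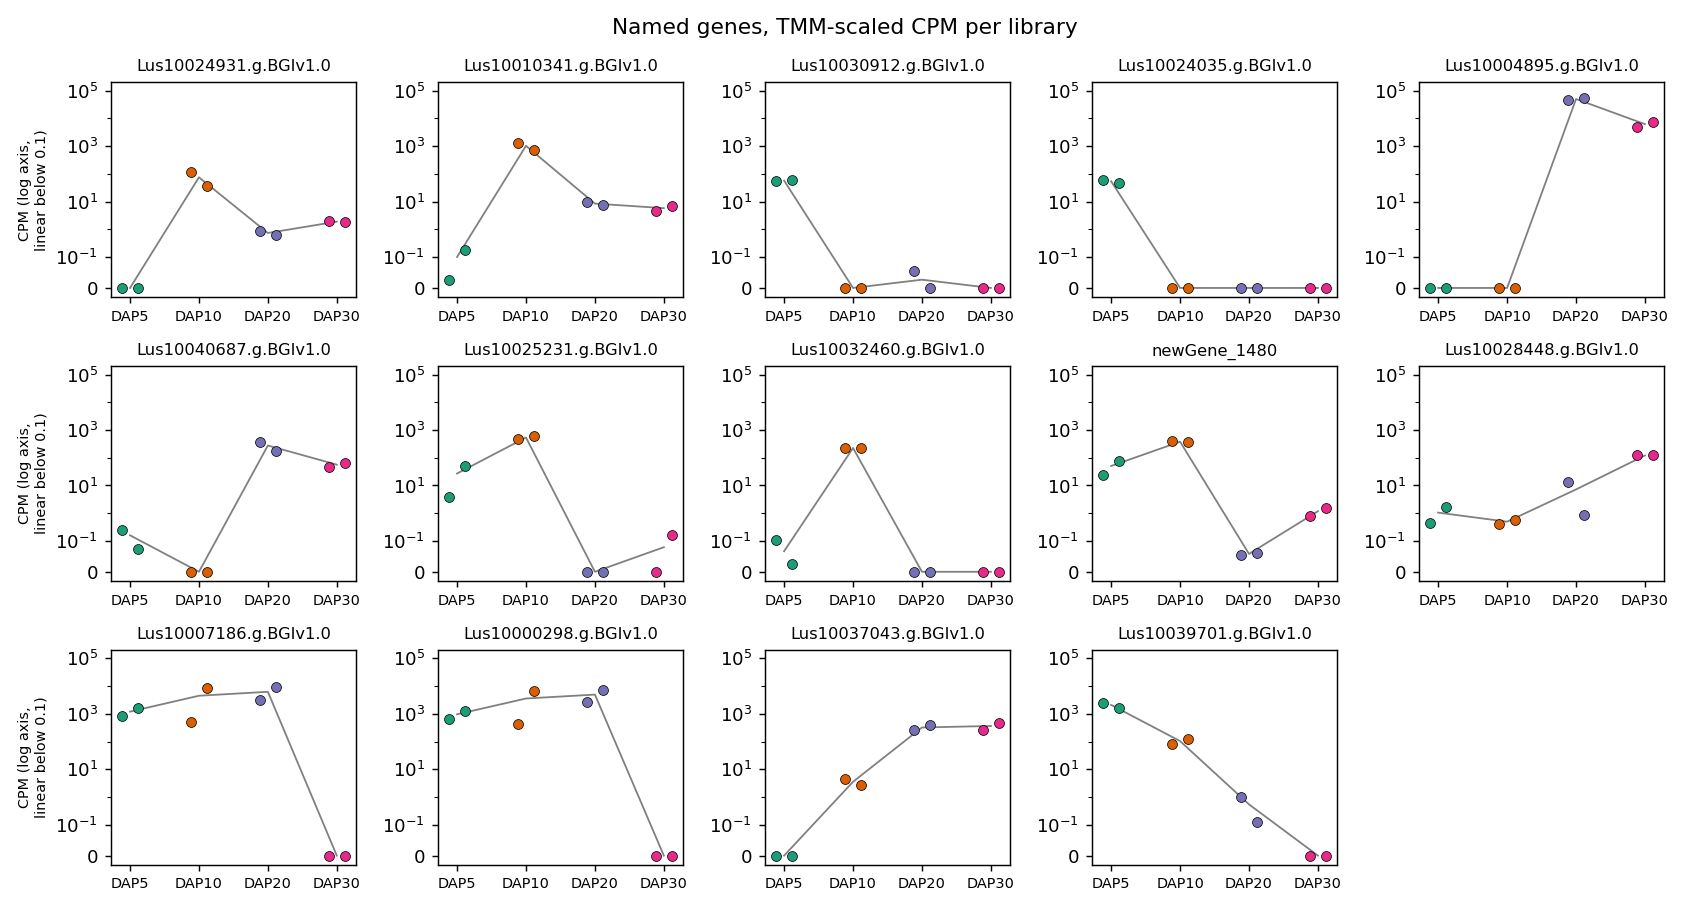
TMM-scaled CPM of the 14 named genes in each library, on an axis that is logarithmic above 0.1 CPM and linear below it. Points are libraries, with replicate 1 to the left, and lines join stage means. Lus10004895.g.BGIv1.0 lies at 0 at DAP5 and DAP10 and at 50100 CPM at DAP20.

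The remaining pairs of stages gave counts between those of the single steps and the whole span. From DAP5 to DAP20, 17430 genes changed, 8335 of them higher and 9095 lower at DAP20. From DAP10 to DAP30, 18955 genes changed, 8411 of them higher and 10544 lower at DAP30. Under library totals the share of called genes that were higher was 22.4% in place of 47.8% for the first pair and 30.3% in place of 44.4% for the second.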

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

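The alternatives in this part were planned. Tests against a 2-fold change called 1683 genes from DAP5 to DAP10, 7508 from DAP10 to DAP20, 2231 from DAP20 to DAP30, 9957 from DAP5 to DAP20 and 12049 from DAP10 to DAP30, fewer by construction. With only the 2 stages compared in the fit, 5796 genes were called from DAP20 to DAP30, and the cause was not tested. The lowest replicate correlation, 0.949 as reported, was 0.935 with a mean of at least 5 CPM and 0.963 with no filter, where other sets of genes entered. With every library kept, 55 other counts under the alternatives stayed within 1.5 times those reported, among them those of DESeq2, which called 7496, 15102, 10036, 17023, 19806 and 18746 genes for DAP5 to DAP10, DAP10 to DAP20, DAP20 to DAP30, DAP5 to DAP20, DAP5 to DAP30 and DAP10 to DAP30. Also among them were the 9671 genes called from DAP5 to DAP10 with only these 2 stages in the fit. That is above the 5796 from DAP20 to DAP30, whereas the shared fit called 6772 and 9338. Which of these 2 steps had more calls thus depends on the fit.

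With each library left out in turn, which leaves a stage with 1 library assumed to vary like the others, counts ran from 1818 to 9204 for DAP5 to DAP10, 10010 to 15100 for DAP10 to DAP20, 4660 to 9390 for DAP20 to DAP30, 14030 to 17306 for DAP5 to DAP20, 17328 to 21544 for DAP5 to DAP30, 15254 to 20141 for DAP10 to DAP30, and 20132 to 23787 across stages. No named gene reversed. Named genes lost their call from DAP20 to DAP30 only, in the test against a 2-fold change, with limma-voom, and without either library of DAP10, DAP20 or DAP30, but not without either library of DAP5. Against a 2-fold change the FDR was 0.108 for Linumusitatissimum_newGene_1480 and 0.0623 for Lus10028448.g.BGIv1.0.

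The replicate numbers are shared between stages, but nothing in the labels says that they pair libraries. Across genes, the replicate differences of 2 stages correlated at 0.00118 to 0.116. With the replicate number as a block, 6138, 14779, 8653, 17050, 19893 and 18589 genes were called for the pairs in the order above and 22238 across stages. Tests of gene lists, with their alternatives, and the alternatives meant for normalized values were not run, since the table holds counts and no gene names. The simulation described above used only the sizes and number of these libraries. How the calling of small fold changes varies with depth or the number of libraries was not tested.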

Other observations

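The patterns in this part were noticed after the data were examined, and the test of DAP10 RNA in DAP20 replicate 1, the alternatives for added gene models and the medians with genes at their bound were chosen only after the result was seen. Genes of different length differed in their changes between DAP10 and DAP20. Among the shortest genes, of 182 to 1223 bases by the authors' length, 1103 of 5757 rose and 1734 fell, with a median log2 fold change of -0.277. Among the longest, of 3223 to 19446 bases, 1983 of 5749 rose and 1182 fell, with a median of 0.264. Under library totals 779 of the shortest rose and 2217 fell, and 1052 of the longest rose and 1708 fell, so the balance of the longest turned. The medians were then -0.669 and -0.13, which kept the longest above the shortest. With genes at 0 in 1 stage set to their bound, the medians under TMM were -0.287 and 0.264. From DAP5 to DAP10 the order was the opposite, with medians of 0.156 for the shortest and -0.124 for the longest genes under TMM and -0.209 and -0.507 under library totals.

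Overlaps of calls between steps differed from pair to pair. The numbers for independent lists take every gene as equally easy to call, which genes of unlike level and spread are not. From DAP10 to DAP20 and then DAP20 to DAP30, 2052 genes rose in both against 1104 for independent lists, 1694 fell in both against 1393, 1225 rose and then fell against 1278, and 689 fell and then rose against 1203. From DAP5 to DAP10 and then DAP10 to DAP20, 1095 rose in both against 909, 1168 fell in both against 892, 1265 rose and then fell against 991, and 761 fell and then rose against 818. Adjacent steps share the libraries of a stage, which pulls their fold changes apart: for the later pair, simulated unchanged stages gave a correlation across genes of -0.489 and a covariance of -0.11, against 0.00125 and 0.00588 observed, and for the earlier pair -0.524 and -0.115, against -0.0126 and -0.0463. The shared libraries could not be divided between the steps with 2 left for each. For DAP5 to DAP10 and DAP20 to DAP30, which share no library, 810 genes rose in both against 536 for independent lists and 595 fell in both against 559, while 713 rose and then fell against 621 and 512 fell and then rose against 483. Their fold changes correlated across genes at -0.0047, against -0.000379 for unchanged stages. Every overlap of this pair exceeded that of independent lists, those in opposite directions included. An excess over independent lists alone therefore does not show that the changes of 2 steps are linked.

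The genes Lus10007186.g.BGIv1.0 and Lus10000298.g.BGIv1.0 had similar ratios between replicates. The level of replicate 2 over replicate 1 was 1.93 and 2 at DAP5, 17.4 and 15.5 at DAP10, and 2.99 and 2.74 at DAP20. Neither had a count at DAP30. Whether they overlap or share reads, and so form 1 signal, was not tested.

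The 2 libraries of DAP20 differed by over 2-fold in 5222 genes, against 1921 to 3111 at the other stages. On a line from the DAP10 mean at 0 to the DAP30 mean at 1, DAP20 replicate 1 lay at 0.613 and replicate 2 at 0.697. Among genes with at least 200 counts in the higher library, 120 were at least 10 times higher in replicate 1 while 18 were in replicate 2. DAP30 RNA mixed into replicate 2 would give the same share from falling and rising genes. But the estimates were 0.624 (95% bootstrap interval 0.58 to 0.679, 396 genes) and -0.00299 (-0.105 to 0.187, 11 genes), a difference of 0.627. Both sets were picked on replicate 1, which can raise either estimate without mixing. With a 4-fold in place of an 8-fold limit they were 0.546 (599 genes) and 0.024 (132 genes). DAP10 RNA mixed into replicate 1 would add 1 share of the DAP10 level to every gene. The log2 ratios of 200 genes spread 6.31 times as widely as 1 share alone allows, but expression by replicate 1 itself would also widen them. The lowest 10% of these genes stood at or below 0.0574% of DAP10. The median was 1.23%, and the low values argue against a share that large. A batch shared by replicate numbers stays open, since the DAP20 difference correlated across genes at no more than 0.116 with that of another stage, between the bounds set beforehand. A difference in developmental progress between the seeds of the 2 libraries is a candidate explanation that was not tested.

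Fewer genes had at least 1 count at DAP30, 28541 ± 573, than at DAP5, 33351 ± 482 (SD, n = 2). Sequencing depth does not account for most of this, because with every library thinned to 12000000 counts 86.4% of the gap remained. A few abundant genes taking the counts at DAP30 would close the gap once removed, but without the 1000 most abundant genes of each library, and with the rest thinned to 5000000 counts, 70.4% of the gap at full depth remained. This share mixes the removal with the lower depth. Thinning to 5000000 counts with these genes kept was not done, so the part due to them alone is not known. The hypothesis that seeds at DAP30 express fewer genes stays open beside differences between stages in RNA quality, which were not tested.

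From DAP5 to DAP30 the median log2 fold change of gene models taken as added by the authors was above that of annotated genes, at 0.39 against -0.268 under TMM and -0.467 against -1.14 under library totals, so their own direction depends on the scaling. Under TMM 381 of them rose and 241 fell, and under library totals 231 rose and 389 fell, against 8608 and 10940 annotated genes under TMM and 4729 and 15529 under library totals. Matching on gene length and expression level did not remove this difference. Against 5 annotated genes matched on both, the difference was 2.28 (95% bootstrap interval 2.05 to 2.54), and 1.94 with genes at 0 in 1 stage set to their bound. The difference was wider after matching because the matched genes had a median of -1.95. The level matched was the mean over all libraries, those of DAP5 and DAP30 included, so the matching may itself have picked genes that fall. It therefore cannot exclude expression level. The interval resamples gene models and does not cover the spread between libraries. The unmatched difference of 0.657 ranged under other settings from 0.44 without DAP30 replicate 1 to 0.886 without DAP5 replicate 2. How the models were built, and reads shared with copies of annotated genes, were not tested.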
